A study of Arabidopsis thaliana with 6 samples.

How the data were processed

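Total RNA of whole seedlings was labelled with Cy3 and hybridised to Agilent arrays, 1 array per condition, per the labels' protocols. The deposited scanner files hold spot intensities extracted with Feature Extraction 11.0.1.1, per the file headers. The intensity used here was the processed signal, which the software had corrected for background, per the file headers. The authors' series matrix holds a linear ratio with no stated scale. Set against the scanner values, it equalled the processed signal divided by the median of its array and then by a value per probe whose origin is not given in the sources used here, and its column medians lay between 0.878 and 1.06. It served as an alternative. The arrays of WT and ago2a lay on slide 1 and both arrays of ago2c on slide 2, so that each slide held both treatments.

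Control spots and spots with an outlier flag were left out, which removed 53 probes, and spots of a probe were averaged on the log2 scale. Values were log2 processed signals minus the 75th percentile of each array. Of the 43603 probes 34348 were matched to a locus through their RefSeq accession, without version, in a gene table of assembly TAIR10.1, and 9255 were not. A probe entered when it was well above background on at least 2 of the 6 arrays, and the brightest probe stood for each of the 20171 loci (6946 of 25410 loci had several probes). Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes) with Benjamini-Hochberg adjustment at 0.05. The irradiation fit had line as a block, the genotype fit had irradiation as a term, and the fit of the response difference had line, irradiation and their interaction with genotype. Their residual degrees of freedom were 2, 3 and 1. Loci at least 2-fold changed were counted per line, with the brighter array well above background, and without a test. Where a locus was dim on every array of a group with all its probes, the fold is a bound against the lowest signal well above background on each array or the locus's own, whichever was higher.

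Gene lists, tests and most alternatives were fixed before the data were examined. Of 18 lists 17 were tested with camera (preset correlation 0.01, and estimated) and fry, and set beside 10000 random lists of matched signal. With an estimated correlation camera has only the residual degrees of freedom of the fit (2, 3 and 1). No list passed that way in any fit (smallest camera adjusted p = 0.51), so a failure there says little about a list. The list of transposable element genes held 17 loci, of which 0 were tested, so it gave no value. Of the 331 loci listed by name 326 had a probe. The named genes were, for irradiation, the 12 highest and 12 lowest past the threshold with the same sign in 3 lines and well above background on the 3 arrays of the brighter treatment, and up to 4 members past the threshold per list. For genotype they were the 8 highest and lowest past the threshold with the same sign in 4 of 4 ago2-WT pairs within a treatment. For the response difference they were the 5 largest each way when fewer than 5 passed, with both ago2 lines on the same side of WT. For single lines they were the 3 largest each way. List members were also named as examples. A member of the damage response list is not reported here by itself and is left out of the plot of that list, but counts in the list's values.

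The alternatives were normexp background correction (offset 50), quantile and median scaling, the authors' values, no filter on dim probes, probes well above background on all 6 arrays, the mean of probes, a trended and a robust eBayes, other blocks, stricter fold thresholds and leaving out each line. The files gave a median but no mean spot signal, so normexp was run on the median signal. The fits were tested on simulated data for 20171 loci, of which 67, 67 and 66 were given changes of 1, 2 and 3 (log2). With variances drawn from the fitted prior, the irradiation fit recovered 19.4%, 82.1% and 93.9% of them and 2.99% of its calls were false, and the genotype fit recovered 31.3%, 70.2% and 92.4% with 8.51% false. With the moderated variance of each locus the false share was 6.63% and 4.46%. The array groups were read from the median of a locus's other probes minus its brightest, by the sign of the first principal component, after the data were seen. Single arrays per condition allow no estimate of the spread between replicates of a condition.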

Results

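Whole-seedling transcripts were measured on 6 single-colour arrays, with 1 array for each combination of 3 lines of Arabidopsis thaliana and 2 treatments. The lines were the Columbia wild type (WT) and the ago2 mutant lines ago2a and ago2c, in which the gene of ARGONAUTE2 (AGO2), a protein that binds small RNAs, is mutated. Seedlings 14 days old received 200 Gy of gamma radiation at 50 Gy per hour over 4 hours, or a mock treatment, and transcripts were measured 24 hours after irradiation. Each array was hybridised with RNA pooled from 3 independent batches of seedlings, so that no condition had a replicate array. Between 70.5% (ago2c mock) and 73.3% (WT irradiated) of the 43603 probes were well above background, no probe was saturated, and 20171 loci were tested. The median signal ran from 229 in ago2c irradiated to 468 in ago2a mock, and the number of arrays limited the precision. In the tests below the lines, or the arrays of a genotype, stood in for replicates. The limma p-values therefore rest on the spread between these pooled samples, moderated by a prior taken over all loci. For the response difference that spread is only the one between ago2a and ago2c, with 1 residual and 3.17 prior degrees of freedom. The camera p-values with a preset correlation set list genes against other genes, so they rest on the spread between genes and not between samples. The arrays also parted by how the probes of 1 locus compared, with both WT arrays and ago2a mock in a first group and ago2a irradiated and both ago2c arrays in a second. Among 5615 loci with several probes well above background on all 6 arrays, the other probes moved by more than 2-fold against the brightest in 0.142% to 0.445% of loci between arrays of a group, and in 10.1% to 17.7% between groups. The mock and irradiated arrays of WT, and those of ago2c, lay within a group, while those of ago2a did not, and the cause was not tested.

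The transcript of the mutated gene was examined first. AGO2 (AT1G31280) was well above background in both WT arrays, with a processed signal of 250.1 in mock and 521 in irradiated seedlings, and in none of the 4 ago2 arrays. The 2 genotypes differed at least 11.5-fold, where the bound sets the mean of the 2 WT arrays against the lowest signal well above background on each dim array. The difference did not pass the limma test across all loci (adjusted p = 0.64). Where the probe lies relative to the mutations was not analysed here. AGO3 (AT1G31290), the neighbouring gene and closest relative of AGO2, was well above background on all 6 arrays, and its 2 probes did not give the same picture. On the brighter probe the ago2 arrays held between 58.5% and 73.8% of the WT signal, whereas on the other ago2a held 114% in mock and 135% in irradiated seedlings and ago2c 48.0% and 57.7%.

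The first comparison asked which transcripts responded to gamma radiation in all 3 lines. SMR7 (AT3G27630), an inhibitor of cyclin-dependent kinases, rose 38.6-fold (log2 5.27 ± 0.15, SE, n = 3 lines; limma adjusted p = 0.012). PARP2 (AT4G02390), a poly(ADP-ribose) polymerase, rose 14.2-fold, BRCA1 (AT4G21070), a homologue of the breast cancer susceptibility gene, 8.73-fold and XRI1 (AT5G48720), named for its induction by X-rays, 8.21-fold. The NAC transcription factor gene ANAC103 (AT5G64060) rose by 3.46 on the log2 scale. AT5G07610 (limma adjusted p = 0.012) was well above background on 2 of the 3 mock arrays. It rose 56.9-fold in WT and 74.7-fold in ago2a, and in ago2c, where the mock array was dim, it was at least 71.7-fold higher. AT5G60250 rose 15.0-fold. The 2 probes of AT4G22960, also named by the fixed rule, disagreed in size. The brighter one was dim on every mock array, and the other, which was well above background in ago2a mock, responded there with 1.35 (log2). Another 4 of the 12 genes that the rule named as higher were not well above background on any mock array with any probe and have only a bound. GEX1 (AT5G55490), a gene first described in gametes, was at least 15.7-fold higher, the cytochrome P450 gene CYP96A11 (AT4G39500) at least 3.96-fold, AT1G32570 at least 3.58-fold and DRM1 (AT5G15380), which belongs to the de novo DNA methyltransferases, at least 3.03-fold. Of the genes that were lower, the small heat shock protein gene HSP23.6 (AT4G25200) fell by 1.98 on the log2 scale and ERF71 (AT2G47520), an ethylene response factor of the hypoxia response, fell by 1.48 in WT and 1.75 in ago2a and was dim in irradiated ago2c. The remaining one, AT2G23270, fell by 1.46 in WT and 1.49 in ago2a, was dim on both ago2c arrays and was named after its values were seen. In total 45 loci were higher and 3 lower at an adjusted p under 0.05 (limma, line as a block), and 2803 had an unadjusted p under 0.05 where 1009 would be expected by chance. These counts depended on the lines and on the processing. With no filter on dim probes 1 of the 48 calls was left, normexp shared 38 of them and probes well above background on all 6 arrays 32. With the array group as a block, chosen after seeing the data and taking no information on irradiation from ago2a, none passed. Without ago2a no locus passed, without ago2c 13 were higher and 6 lower, and without WT 139 were higher and 943 lower. The fixed rule named 14 of the 48 genes and asked for the same sign in all 3 lines. Their direction could therefore not change when a line was left out, and is no check.

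Among the transcripts known to depend on the damage regulator SOG1, 25 were measured, of which 13 rose, none fell and 12 did not pass the test. When adjusted over the list alone, 23 were higher. GMI1 (AT5G24280) rose 7.32-fold, the ribonucleotide reductase gene TSO2 (AT3G27060) 5.74-fold and the thymidine kinase gene TK1A (AT3G07800) 6.22-fold. The mitotic cyclin gene CYCB1;1 (AT4G37490) had a log2 difference of 2.05 with an adjusted p of 0.051 (limma). The list's median was 2.17 (log2), with 1.98 in WT, 2.30 in ago2a and 2.09 in ago2c, each above all of 10000 random lists of matched signal. The list stood apart from other genes with a preset correlation (camera adjusted p = 1.3e-30) but not with an estimated one (adjusted p = 0.51 with an estimated correlation), and its genes moved one way on balance by fry (adjusted p = 0.019). CEN2 (AT4G37010), a centrin, was the member with the widest spread, at 0.65 in WT, -1.09 in ago2a and -1.55 in ago2c.

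**Figure D1:**
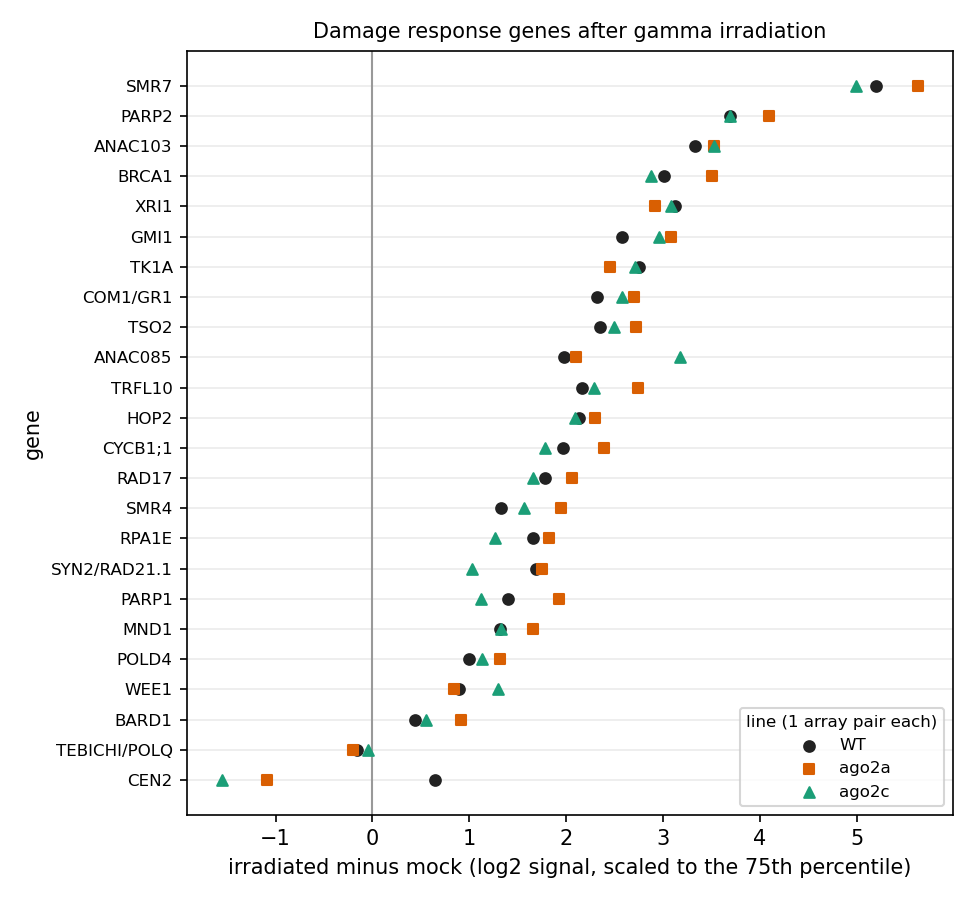
Irradiated minus mock difference (horizontal axis, log2 signal scaled to the 75th percentile of each array) of 24 of the 25 measured damage response genes (vertical axis), with a circle for WT, a square for ago2a and a triangle for ago2c, each from a single pair of arrays. The medians of all 25 were 1.98, 2.30 and 2.09, and SMR7 lay highest in all 3 lines.

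Other fixed lists shifted by smaller amounts after irradiation. Of 27 measured genes of DNA replication and S phase none passed the test over all loci, and 23 were higher when adjusted over the list alone. Their median was 0.53 (camera adjusted p = 3.1e-16, and adjusted p = 0.60 with an estimated correlation), with RNR1, a subunit of ribonucleotide reductase, at 1.36 and the sliding clamp gene PCNA1 at 0.84. Of 16 heat shock and chaperone genes 1, HSP23.6, fell, and when adjusted over the list alone 11 were lower and 3 higher. Their median was -0.85 (camera adjusted p = 2.8e-06, and adjusted p = 0.51 with an estimated correlation), with HSFA2 at -1.92 and HSP101 at -0.89. The endoplasmic reticulum chaperones BIP1 and BIP2 of that list had values of 0.59 and 0.54, and BIP3, dim on every mock array, was at least 1.77-fold higher. The medians of 20 genes of abscisic acid, drought and cold (0.28; camera adjusted p = 2.8e-06), 24 of other break repair machinery (0.11; 0.0025), 26 of the G2/M cell cycle (-0.25; 0.00014), 24 nuclear genes of photosynthesis (0.15; 0.0060; -0.020 after quantile normalization and 0.02, not past the threshold, with the mean of probes), 21 of flavonoid and anthocyanin synthesis (-0.14; 0.028) and 18 root markers (-1.15; 3.7e-05) were also past the threshold of camera with the preset correlation. In 3 of these lists WT did not share the shift: root markers, whose values per line are given below, photosynthesis genes (-0.03 in WT, 0.36 in ago2a and 0.12 in ago2c) and flavonoid genes (0.08, -0.44 and -0.05). In the last 2 WT had the opposite sign and ago2a, whose arrays lay in different array groups, the largest value. G2/M genes were lowest in WT, with medians of -0.47 in WT, -0.23 in ago2a and -0.14 in ago2c. These lay at percentiles 0, 3.92 and 3.16 of random lists of matched signal. With an estimated correlation the adjusted p-values of these 6 lists were 0.51 for the first and 0.64 for each of the others. By fry these 6 lists did not pass either, with adjusted p-values between 0.10 and 0.52. Heat shock and chaperone genes (fry adjusted p = 0.052) and DNA replication genes (0.089) did not pass by fry. Lists of the small RNA pathway (median 0.10; camera adjusted p = 0.17), copper microRNA targets (-0.10; 0.31), antioxidant genes (0.07; 0.95), salicylic acid and defence (-0.12; 0.21), jasmonate and wounding (-0.11; 0.40), senescence (0.16; 0.33), shoot meristem and floral transition (-0.05; 0.40) and 7 cytosolic ribosomal protein genes (-0.0069; 0.74) did not pass.

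Within each line the response was counted without a test, since each rested on 1 mock and 1 irradiated array. In WT 257 loci were at least 2-fold higher and 317 at least 2-fold lower after irradiation. In ago2a 280 were higher and 1491 lower, and in ago2c 256 were higher and 1110 lower. The ago2a counts set arrays of different array groups against each other and depended on the probe. Among the 5615 loci with several bright probes, 128 were at least 2-fold lower in ago2a by the brightest probe and 761 by the median of the others, against 123 and 119 in ago2c and 19 and 25 in WT. The share of higher loci was 44.8% in WT, 15.8% in ago2a and 18.7% in ago2c. Scaling to the median of each array moved the ago2a split to 496 higher and 1107 lower (30.9% higher). That scaling raised the median response of all loci in ago2a from 0.06 to 0.25 (log2) and in ago2c from 0.01 to 0.08, so the excess of lower loci in ago2a is relative to that shift. The counts moved with other settings as well. After normexp they were 122 higher and 143 lower in WT, 159 and 635 in ago2a, and 70 and 562 in ago2c. The authors' values gave 815 higher in ago2a, and probes well above background on all 6 arrays gave 134 higher and 148 lower in WT, 173 and 943 in ago2a, and 135 higher in ago2c. At least 2-fold higher in all 3 lines were 84 loci, against 0.045 expected from independent lists. Of the lower loci, 52 were shared by all 3 lines (1.29 expected), 753 by ago2a and ago2c (82.1 expected), 177 by WT and ago2a (23.4) and 81 by WT and ago2c (17.44). Both ago2 lines but not WT had 701 lower loci, and WT and neither ago2 line had 111. The higher loci did not set the ago2 lines apart in this way. WT and ago2a shared 99 of them, WT and ago2c 114, and ago2a and ago2c 115. Both ago2 lines but not WT had 31 higher loci, and WT and neither ago2 line had 128. Across loci, which are not independent replicates, the responses correlated with r = 0.60 (rho = 0.52) between ago2a and ago2c, 0.26 (0.11) between WT and ago2a and 0.28 (0.28) between WT and ago2c. The rule for single lines took values that include dim arrays, so the order of the genes it named is not established. It named AT5G07610 and the brighter probe of AT4G22960 in every line, GEX1 in WT and ago2c and SMR7 in ago2a as higher. As lower it named AT4G16050, AT3G57970 and AT1G01450 in WT, AT4G10860, AT1G11040 and AT5G50345 in ago2a, and AT5G04120, AT4G04423 and AT3G25960 in ago2c. These 9 were not well above background after irradiation in that line, with bounds from at least 3.94-fold (AT3G25960) to at least 6.63-fold (AT1G11040) lower.

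**Figure D2:**
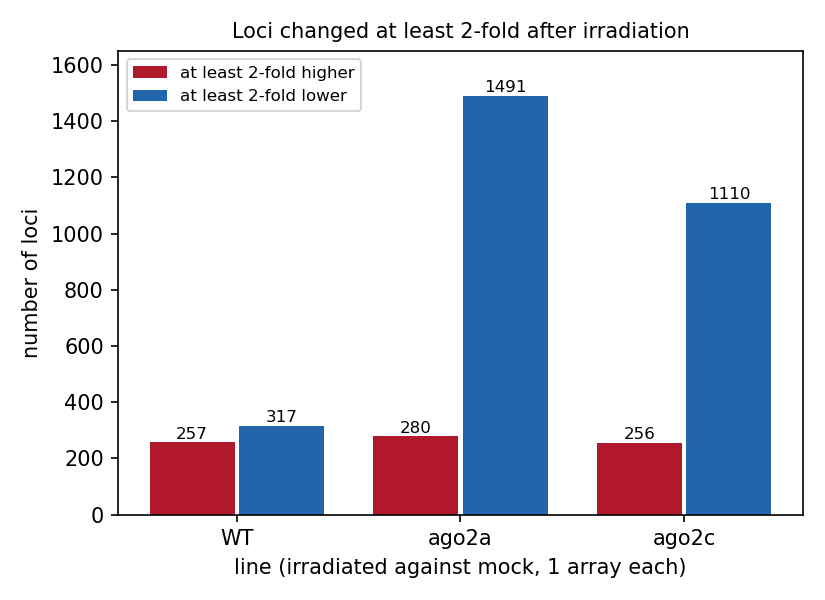
Number of loci (vertical axis) at least 2-fold higher or lower in irradiated than in mock seedlings of each line, from 1 array per treatment and the main scaling. Lower loci numbered 317 in WT, 1491 in ago2a and 1110 in ago2c, while higher loci numbered between 256 and 280. The ago2a arrays lay in different array groups, and their counts depended on the probe.

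The second comparison set the 4 ago2 arrays against the 2 WT arrays, with irradiation as a term. It had no line term, so the mock and irradiated arrays of a line counted as separate samples. WT was a single line, so a difference between its cultures and the others cannot be told from genotype. A single locus, AT3G28899, was lower in the ago2 lines (limma adjusted p = 0.038). It was well above background in both WT arrays and in no ago2 array, and at least 2.93-fold lower. It was lower in 4 of 4 pairs, as the naming rule required. No locus was higher by limma, and 793 had an unadjusted p under 0.05 where 1009 would be expected by chance. The call was lost with normexp, with no filter on dim probes, with a trended eBayes, in the mock arrays alone, without ago2a, with the array group as a block, and with the slide as a block, which called 3 loci higher and none lower. It was not tested with probes well above background on all 6 arrays. In the fixed lists, 10 of 10 measured targets of copper microRNAs and MEMB12 had lower values in the ago2 lines, with a median of -0.37 and none past the test (camera adjusted p = 0.00079, and adjusted p = 0.64 with an estimated correlation). Laccase genes LAC12 and LAC3 were at -0.93 and -0.93, and the superoxide dismutase genes CSD1 and CSD2 at -0.13 and -0.14. Abscisic acid genes (0.26; camera adjusted p = 0.0017), photosynthesis genes (0.25; 0.0024; -0.0078 after quantile normalization and -0.065 with the mean of probes), small RNA pathway genes (0.19; 0.025), other break repair genes (0.13; 0.030), senescence genes (-0.13; 0.042), shoot meristem genes (-0.34; 0.038) and root markers (-0.89; 0.00014) also passed with the preset correlation. With an estimated correlation their adjusted p-values lay between 0.64 and 0.97. By fry the adjusted p-values of these lists and of the copper targets lay between 0.45 and 0.81. In mock seedlings alone the medians were -0.16 for root markers and -0.15 for shoot meristem genes. Copper targets were there at -0.37, abscisic acid genes at 0.18, photosynthesis genes at 0.11 and senescence genes at -0.19. Small RNA pathway genes were at 0.086 and other break repair genes at 0.040. These mock values rest on a single WT array. The genotype values also mixed the array groups. With the array group as a block photosynthesis genes were at -0.15, small RNA pathway genes at -0.03 and other break repair genes at -0.02. These were opposite in sign, and copper targets were at -0.11 and root markers at -0.14. In that fit ago2a mock was the only ago2 array in the group of the WT arrays. The genotype values thus rested on this 1 array against WT, and how much of the shifts the array group explains cannot be told from them. In the damage response list the genotypes had a median difference of 0.04 (camera adjusted p = 0.98).

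The third comparison, between the radiation responses of the ago2 lines and of WT, is the one named by the title of the series. No locus passed the test of this difference in either direction (limma, smallest adjusted p = 0.16), and 1779 had an unadjusted p under 0.05 where 1009 would be expected. The fit had 1 residual degree of freedom, which was the difference between the responses of ago2a and ago2c. The WT pair added no spread and was assumed to vary like the ago2 pairs, so a peculiarity of that pair cannot be told from genotype. The ago2a arrays also lay in different array groups, so any effect of the groups entered this spread. In simulated data 67, 67 and 66 of 20171 loci were given changes of 1, 2 and 3 (log2). With variances drawn from its fitted prior the fit recovered 0% of each. With each locus's moderated variance it recovered 20.9%, 98.5% and 100% of them, but 31.8% of its calls were false. That simulated fit had 10.75 prior degrees of freedom against 3.17 in the real one, so these shares do not carry over to the data. Other processing called many loci (101 higher and 536 lower after median scaling, 18 and 523 after normexp). The median-scaled fit had infinite prior degrees of freedom and so gave all loci a common variance. Quantile normalization, no filter on dim probes and the mean of probes called none, and probes well above background on all 6 arrays called 1. The rule named ATCHX13, AT1G01450, RALFL2, AT5G36001 and AT5G28660 as higher and AT3G25960, TPS2, AT3G06090, AT1G50350 and AT4G08800 as lower, none past the threshold. Each of these 10 was well above background on 2 to 4 of the 6 arrays, so their sizes and order are not established. In TPS2 (AT1G16980) 1 array of each pair was dim, mock in WT and irradiated in both ago2 lines. The damage response list differed by a median of 0.17 (camera adjusted p = 0.30).

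The fixed list of root markers had lower values after irradiation in both ago2 lines. Its 18 measured genes had a median response of -0.04 in WT, -1.58 in ago2a and -1.65 in ago2c, and a median difference of -1.57 between the ago2 lines and WT. None passed over all loci, and when adjusted over the list alone 11 were lower and 1 higher. The list passed with the preset correlation (camera adjusted p = 2.5e-10) but not otherwise (adjusted p = 0.82 with an estimated correlation, and 0.50 by fry). The estimated correlation was -0.046, below the preset 0.01, so the loss with camera did not come from a higher correlation between genes. That test had 1 residual degree of freedom. The root hair expansin EXPA7 responded with 0.23 in WT, -2.44 in ago2a and -2.59 in ago2c, and CASP1, of the endodermal Casparian strip, with -0.10, -1.73 and -1.79. SCR and SHR, regulators of root patterning, were near 0 in all lines, with 0.42 the largest value (SCR in ago2a). Of the 18 markers 4 were dim on some arrays: NRT2.1 in irradiated WT and in both ago2 mock arrays, CASP4 and CASP5 in both irradiated ago2 arrays, CASP5 also in ago2c mock, and PLT1 on every irradiated array. The other 14 had medians of 0.07 in WT, -1.58 in ago2a and -1.55 in ago2c. In mock seedlings the list's median difference between the ago2 lines and WT was -0.16. Beside this, photosynthesis genes (median difference 0.29; camera adjusted p = 0.0023), DNA replication genes (0.24; 0.0023), G2/M genes (0.23; 0.0067) and flavonoid genes (-0.34; 0.0023) passed with the preset correlation, and none with an estimated one (adjusted p = 0.82 for each). By fry the adjusted p-value was 0.83 for each of these 4 lists. For photosynthesis and flavonoid genes ago2a, whose arrays lay in different array groups, was further from WT than ago2c, by the medians per line given above. None of these 4 lists passed after median scaling, and photosynthesis genes did not pass with the mean of probes (0.11; 0.115) or after quantile normalization (0.04; 0.98).

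**Figure D3:**
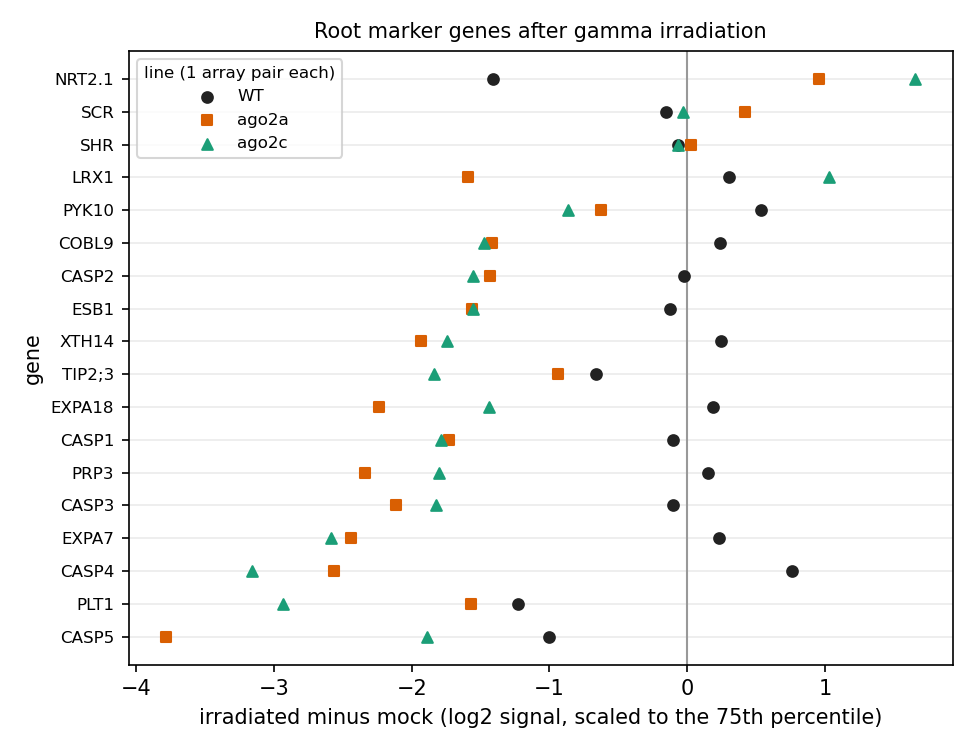
Irradiated minus mock difference (horizontal axis, log2 signal scaled to the 75th percentile of each array) of the 18 measured root markers (vertical axis), with a circle for WT, a square for ago2a and a triangle for ago2c, each from a single pair of arrays. The list's medians were -0.04, -1.58 and -1.65, and SCR, SHR, NRT2.1 and, in ago2c, LRX1 did not share the lower values of the ago2 lines. NRT2.1, CASP4, CASP5 and PLT1 were dim on some arrays.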

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

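The tests of array scaling, of slide and of array group in this part were chosen after the result was seen.

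The response to irradiation differed between the ago2 lines and WT, by camera with the preset correlation, for root markers (median difference -1.57), photosynthesis genes (0.29), DNA replication genes (0.24), G2/M genes (0.23) and flavonoid genes (-0.34). None of the 5 passed with an estimated correlation or by fry. Photosynthesis genes lay at the 92.5th percentile of random lists of matched signal for this difference, and DNA replication genes at the 99.8th. Flavonoid and photosynthesis genes had median responses of 0.08 and -0.03 in WT, -0.44 and 0.36 in ago2a, and -0.05 and 0.12 in ago2c, where they lay at the 17.7th and 63.1st percentile. The difference for these 2 lists was therefore largest in ago2a, whose arrays lie in different array groups, and how much of it the array group explains was not tested.

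For the root markers, array scaling is argued against: over 5 scalings the difference nearest 0 was -1.31. A slide effect is argued against as well, since ago2a, on the slide of WT, differed from WT by -1.64. The array group of the probe offsets is argued against too, since ago2c, with both arrays in 1 group, differed from WT by -1.58. Each holds for that explanation as the only cause, as ago2a crosses the array groups and ago2c lies on the other slide. Less root tissue in the irradiated ago2 samples stays open. It was predicted, after the list's median was seen but before its subsets were compared, that root hair, endodermis and other root markers would then fall by similar amounts, and that a range of their medians above 1 (log2) with a permutation p under 0.05 would speak against it. The medians were -1.84, -1.87 and -0.38, a range of 1.48 with a permutation p of 0.044, so the stated bound was met, but by less than the bootstrap SD of the range (0.68), and it is therefore not read as excluding the explanation. That comparison with the SD was added after the range was seen. The outcome rests on few genes: a first run left out SCR, SHR and PLT2, a choice made after the prediction was written, and gave a range of 0.80 with a permutation p of 0.19. A transcriptional effect of the genotype on root genes under irradiation, which the design names, is likewise open and untested, as organs were not separated.

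Irradiation called 48 loci, and the highest count of the other 9 splits of the 6 arrays was 0. The other splits part only 1 line's pair of arrays or leave the irradiation response in the residual, so their low counts say little. With 10 splits in all, of which 1 gave as many, a share under 0.05 cannot be reached.

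Data outside the comparisons were the probes without a locus. Of these 4183 were well above background on at least 2 arrays, 0 passed the limma test for irradiation, and 328 had an unadjusted p under 0.05.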

How the results depend on the processing

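The damage response list kept its direction and side of the threshold under the 7 other scalings, filters and probe rules (median 1.79 to 2.26), without the line block, by fry and without any line (2.11 to 2.19), and lost it with an estimated correlation (median 2.17; adjusted p = 0.51). The root marker difference kept both under the same 7 settings (-1.66 to -1.31) and lost its call with an estimated correlation (-1.57) and by fry (-1.57), tests fixed beforehand for every list, but counted as alternatives for this result only after seeing the data. The correlations between lines moved by less than the SD of the main correlations across the line pairs. That SD measures how the pairs differ and not the uncertainty of a correlation, so a sizeable move could pass.

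With normexp 34 loci were lower after irradiation, 0 were lower in ago2, and response differences numbered 18 higher and 523 lower. Its 2-fold counts were 122 higher and 143 lower in WT, 159 and 635 in ago2a, and 70 and 562 in ago2c. Quantile normalization gave 5 lower after irradiation, and turned the photosynthesis median to -0.020 for irradiation and to -0.0078 for genotype, which the mean of probes turned to -0.065. Median scaling gave 71 higher and 17 lower after irradiation, response differences of 101 higher and 536 lower, and 496 loci 2-fold higher in ago2a. The authors' values gave 5 lower after irradiation, response differences of 77 higher and 598 lower, and 815 loci 2-fold higher in ago2a. They also changed the probe that stood for 2077 loci, as the brightest was chosen anew in each setting (215 loci with normexp and 5 with quantile normalization). With the probes of the main setting, an alternative added after seeing the data, the authors' values gave 68 higher and 14 lower after irradiation, response differences of 101 higher and 539 lower, and 494 loci 2-fold higher in ago2a. With no filter on dim probes 1 locus was higher and 0 lower after irradiation and 0 lower in ago2. With probes well above background on all 6 arrays 23 were lower after irradiation, 0 lower in ago2 and 1 response difference was lower, and 2-fold counts were 134 higher and 148 lower in WT, 173 and 943 in ago2a, and 135 higher in ago2c; fewer loci were tested there. At 3-fold, a stricter threshold by construction, the counts were 106 higher and 138 lower in WT, 112 and 602 in ago2a, and 144 and 486 in ago2c. A trended eBayes gave 68 higher and 29 lower after irradiation, 0 lower in ago2, and 3 higher and 209 lower response differences. Without the line term, that is with no replicate block, irradiation called 84 higher and 19 lower. The array group as a block, added after seeing the data, gave 0 higher and 0 lower after irradiation. It turned genotype medians to -0.15 for photosynthesis, -0.034 for the small RNA pathway and -0.024 for other break repair. These genotype values rested on ago2a mock alone against WT. The slide as a block gave 3 higher and 0 lower in ago2, and the mock arrays alone 0 lower. Leaving out 1 line moved the irradiation counts between 0 and 139 higher and between 0 and 943 lower; leaving out ago2c, which is slide 1 alone, gave 13 and 6. For ago2, leaving out ago2a gave 0 higher and 0 lower and leaving out ago2c gave 3 higher. Except for the prior variance behind the response differences and the thresholds and filters that act by construction, the cause was not tested. The slide block was not run for irradiation and the response difference, where it lies within the line block, and neither a line could be left out of the response difference nor the array group added, as it has 1 residual degree of freedom. The labels carry no replicate numbers, and the line block pairs the mock and irradiated array of each line. Signals near background limited the single-line counts: 327 of the 1491 lower loci of ago2a were dim after irradiation on all their probes.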

Other observations

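The prior variance test and the gene families in this part were chosen after the results were seen.

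Genes were also grouped by the letters of their symbol, which gave 208 families of at least 8 tested members. For the response difference 24 families passed camera with the preset correlation, 0 with an estimated correlation and 0 by fry. The family with the smallest adjusted p was RHS, the root hair specific genes, with 9 members of which 9 were lower (median difference -1.88; camera adjusted p = 9.2e-11, and 0.94 with an estimated correlation). Their median response was 0.21 in WT, -1.79 in ago2a and -1.53 in ago2c. XTH genes, which encode enzymes that remodel xyloglucan of the cell wall, had a median difference of -0.79 with 21 of 26 members lower (camera adjusted p = 7.2e-06). XTH14 is also on the fixed list of root markers. EMB genes, named for embryo defects of their mutants, had a median difference of 0.24 with 128 of 150 members higher (camera adjusted p = 4.3e-05). The medians of these 3 families kept their sign under each other scaling, filter and probe rule.

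Some single genes differed widely between genotypes without passing the limma test, and were chosen after their values were seen. PR1 (AT2G14610), a marker of salicylic acid defence, differed from WT by -3.23 in mock and -3.98 in irradiated ago2a (log2), and was dim on both ago2c arrays. DXPS1 (AT3G21500) differed by -2.99 (ago2 minus WT), and AT5G46295, not well above background in WT, was at least 20.7-fold higher in the ago2 lines. Each held its direction in 4 of 4 pairs, with a limma adjusted p of 0.64. These pairs share the WT arrays and the genes were picked for a large difference, so the pairs are not independent checks. MRD1 (AT1G53480) differed from WT by 5.01 and 5.40 in ago2a but by 0.87 and 0.71 in ago2c.

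PEL3 (AT5G23940) stood at 6.54 (log2, relative to the 75th percentile) in irradiated WT and between 1.79 and 2.18 on the other 5 arrays. A spot or probe artefact could not be tested by the planned comparison of probes, because 0 other probes of the locus were well above background.

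The number of response differences moved from 0 to 637 with median scaling. A candidate explanation is the prior variance that eBayes estimates from 1 residual degree of freedom. With the prior of the 75th percentile fit (3.17 prior degrees of freedom) the median-scaled values called 0 loci. With the prior of the median-scaled fit the values scaled to the 75th percentile called 808. That prior had infinite degrees of freedom, so all loci had a common variance and the spread of each locus was not used. The calls after median scaling and after normexp shared 301 loci. These values fit a count set by the prior, and leave open how many of the called loci differ.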
